A study of Arabidopsis thaliana with 72 samples.

How the data were processed

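Whole Arabidopsis seedlings, 7 days old and grown at 22 °C, were profiled on 72 Affymetrix ATH1 arrays after mock treatment or treatment with 1 of 7 plant hormones. The arrays form 36 groups of 2, from 3 genotypes and 3 times (30 min, 1 h and 3 h). Per the labels, arrays of one genotype and one time form a lettered set, which gives 9 sets, so genotype and time each coincide with set. The labels do not say that the 2 arrays of a group came from separate cultures, so p-values measure the spread between these arrays, which may be technical. The number of arrays limits the precision of every value.

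The deposited values are linear signal intensities, 1 per probe set and array, made with MAS5 per the submitters' processing notes. Scanner files, scan dates and detection calls were not used here. The table held 22810 probe sets, of which 64 were controls and were left out of the tests. The 2% trimmed means of the deposited arrays lay between 871 and 1158 in Col-0 and between 1810 and 2963 in the mutants. The largest deviation from their median was 158.2%, above the 10% tolerance set before the data were examined, so each array was scaled to a common trimmed mean of 1147. Arrays of one set and replicate number shared nearly the same trimmed mean, except ACC 3 h replicate 1, whose 1148 was near that of the 30 min set (1147) and not of its own set (1045).

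One array, Col-0 IAA 30 min replicate 2, held impossible intensities (zeros, negative values and values up to 4.26866e+32) in 2 stretches of 1700 and 273 consecutive probe sets. These 1973 probe sets were treated as missing on that array, by a rule chosen after the data were seen, and 1456 of them were among those tested. For these the IAA value at 30 min rests on 1 treated array.

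From the scaled intensities, log2(signal + 55) was computed, where 55 is 10% of the median deposited signal. A fold change on this scale understates the change of dim probe sets. A probe set was tested where its signal exceeded the 40th percentile of the array on at least 2 arrays, which left 17262. limma 3.58.1 in R 4.3.3 fitted 1 mean per group over all 72 arrays (36 residual degrees of freedom), with eBayes and an intensity trend. A moderated F over the 3 times gave the calls of each treatment against its own mock, and moderated t statistics gave direction and calls at single times. Mutant and Col-0 mock seedlings were compared as the mean over the times, a difference of response between genotypes by the interaction F, and mock seedlings over time as 3 h against 30 min. Adjusted p-values are limma's with Benjamini-Hochberg adjustment at a threshold of 0.05.

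The fit was tested on simulated data for all 72 arrays. Values were drawn independently around the mean of each probe set over all arrays, with its residual spread from the fit. They lack the correlation of same-numbered arrays found in the data, so the share of false calls may differ there. In the Col-0 IAA arrays, 50 of 17262 probe sets were changed by each size, equally at the 3 times. The fit recovered 48% of changes of 0.5 on the log2 scale, 86% of changes of 1, 100% of 1.5 and 98% of 2, and 8 of 174 calls were false. At 3 h alone it recovered 14%, 54%, 84% and 96% of these sizes.

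The 23 gene lists (326 genes) were fixed before the data were examined. The platform annotation used here names 1 gene for 13513 probe sets and several for 503, and 8730 are unnamed here. Symbols of 13436 probe sets were updated through the Entrez identifier. Only 40 list genes had a tested probe set, and the lists of brassinosteroid biosynthesis, brassinosteroid signalling, cell cycle, PP2C phosphatases, cytokinin metabolism, gibberellin metabolism, JAZ repressors, PYR/PYL receptors and SAUR groups had none. GA1 and DET2, the genes mutated in ga1-5 and det2-1, are not named by any probe set here, so the mutants' labels could not be checked on them. Lists with at least 3 tested genes were tested with camera on pre-ranked z statistics of the mean over the times (inter-gene correlation 0.01, and again with an estimated correlation), because missing values rule out camera itself, with adjustment over 54 tests. Families sharing a symbol stem, with at least 6 tested genes, were added after the annotation and the numbers of calls had been seen.

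Genes were named by a rule fixed beforehand. For each treatment, at the time with the most calls, it took the 8 largest rises and 6 largest falls among called probe sets that name 1 gene and whose 2 treated arrays both lay above, or both below, the mock arrays. It also took up to 4 members of each list with the smallest adjusted p. The same 8 and 6 were taken for the mutants, the genotype differences and mock over time.

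Replicate numbers come from the labels. Deviations of same-numbered treated and mock arrays from their group means correlated above 0.1 at all times for IAA (lowest 0.269), zeatin (0.317), GA3 in Col-0 (0.273), ABA (0.135) and BL in det2-1 (0.145), and these were taken as paired. The other treatments did not meet this at every time. The pairing decided only which splits of the arrays were counted. Calls, adjusted p-values and list tests come from the fit without a replicate block, also for the paired treatments, unless a block is stated. These correlations and the numbers of calls with and without a block were first seen together, so only the fixed threshold decided the pairing. Alternatives covered the filter, normalization, pseudocount, variance trend, arrays in the fit, a replicate block and leaving out each array. Added after the data were seen were the deposited scale without rescaling, leaving out the probe sets with impossible values, and leaving out the 4 det2-1 arrays at 30 min. On the deposited scale the 2 arrays of a group differ in overall level (trimmed means 1147 and 871.4 in the Col-0 30 min set). This difference enters the spread of the probe sets, so a hormone call lost there says little on the single gene.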

Results

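The arrays measured transcript levels in seedlings of Col-0, of ga1-5 (deficient in gibberellin) and of det2-1 (deficient in brassinosteroid). Col-0 received indole-3-acetic acid (IAA, an auxin), zeatin (a cytokinin), gibberellin A3 (GA3), abscisic acid (ABA), methyl jasmonate (MJ), the ethylene precursor ACC or brassinolide (BL, a brassinosteroid), while ga1-5 received GA3 and det2-1 received BL. Doses were 1 µM for IAA, zeatin and GA3, 10 µM for ABA, MJ and ACC, and 10 nM for BL. Each group had 2 arrays, and replicate arrays correlated at 0.936 to 0.979 across probe sets (median 0.9645). Arrays of different groups in one set correlated nearly as highly, with medians of 0.9556 for the same replicate number and 0.9473 for different numbers. Because the doses differ, the numbers of calls do not rank the hormones.

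**Figure D1:**
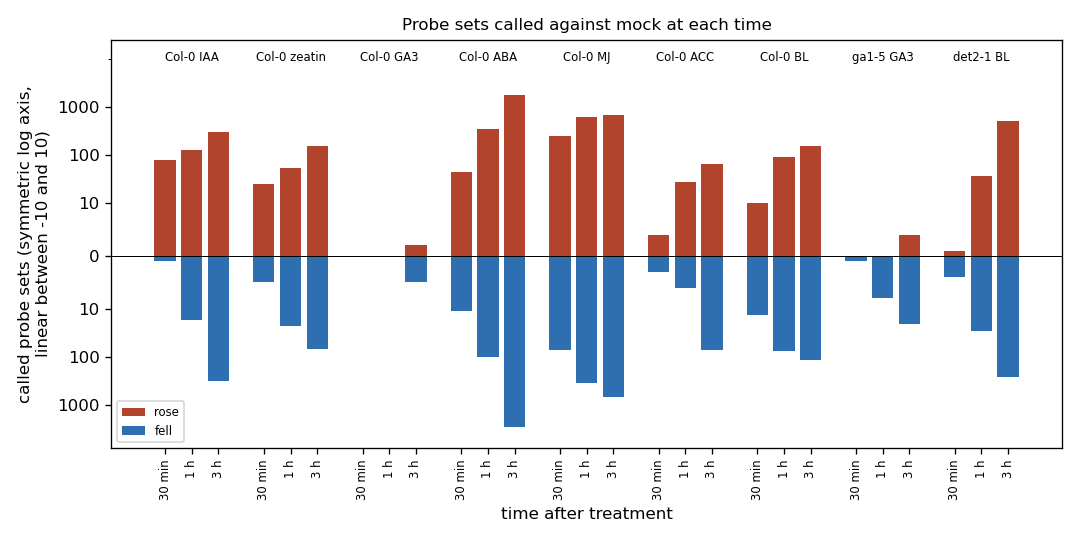
Probe sets called against mock (limma, adjusted p under 0.05) at each time, on a symmetric log axis that is linear between -10 and 10, with rises above and falls below 0. ABA at 3 h has 1756 rises and 2859 falls, and GA3 in Col-0 has none before 3 h.

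IAA raised the genes of early auxin response within 30 min. GH3.3, which conjugates auxin to amino acids, rose 12.6-fold at 30 min (1 treated array), 40.2-fold at 1 h and 38.7-fold at 3 h (log2 change 5.27, SE 0.25, n = 2 arrays per group, limma adjusted p = 2.5e-19). Of the 7 tested genes of early auxin response outside the Aux/IAA family, 5 rose at 30 min and 6 at 3 h, and 6 adjusted over the list alone. LBD29, a regulator of lateral root formation, rose 15.8-fold at 3 h, GH3.5 (WES1) 12.6-fold and HAT2 6.62-fold, while GH3.17 had a log2 change of -0.21 and did not pass. Of 6 tested Aux/IAA repressors, IAA29 (15.3-fold) and IAA30 (7.13-fold) rose at 3 h, and 3 adjusted over the list alone. Both lists shifted upward (camera adjusted p = 7.16e-45 and 9.97e-08). Early calls were nearly all rises, with 77 against 1 fall at 30 min, while 297 rose and 320 fell at 3 h (505 and 600 with the replicate block). Leaving out 1 of the 4 arrays compared gave 33 to 60 calls at 30 min and 346 to 481 at 3 h. On the deposited scale without rescaling 105 rose and 63 fell at 3 h. XTH21, a cell wall enzyme gene, fell by 2.35 on the log2 scale, and was not called without mock 3 h replicate 1 (-1.91, adjusted p = 0.0732) or with only the arrays of the sets used (0.0575). Growth and ethylene genes also shifted upward (adjusted p = 1.72e-07 and 0.00382), and in each 2 of 3 tested genes rose at 3 h, and 2 adjusted over the list alone. XTH19 rose 3.57-fold and ARL 2.28-fold. Over the time course 528 probe sets were called, and 954 with the replicate block.

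Zeatin raised both tested type-A response regulators, which act in cytokinin feedback. ARR15 rose 10.2-fold and ARR16 4.65-fold at 30 min, and 6.11-fold and 4.33-fold at 1 h. At 3 h ARR16 rose 3.32-fold while ARR15 was at 2.76-fold and did not pass (adjusted p = 0.0863). Of these 2 genes, 1 rose at 3 h, and 2 adjusted over the list alone. The beta-glucosidase gene BGLU28 rose 5.89-fold at 3 h (SE 0.53, adjusted p = 0.00674), but was not called without mock 3 h replicate 1 or zeatin 3 h replicate 1 (adjusted p = 0.078 and 0.0916), and AT2G25150 rose 8.74-fold. AT4G33420 fell by 1.30 (SE 0.14). On the deposited scale the 3 h calls of ARR16, BGLU28, AT2G25150 and AT4G33420 ended (adjusted p = 0.118, 0.178, 0.0897 and 0.0896), and AT2G25150 also with only the arrays of the sets used (0.136). The time course held 233 calls, and 582 with the replicate block. It held 142 without zeatin 3 h replicate 2, and 155 without mock 1 h replicate 2.

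GA3 changed few probe sets in either genotype. At 3 h 4 rose and 21 fell in ga1-5 (3 and 4 on the deposited scale, 30 and 81 with the replicate block). In Col-0 2 rose and 5 fell (10 and 22 with the replicate block). The ga1-5 count at 3 h was over 1.5 times lower without any 1 of its 4 arrays. The Col-0 count was over 1.5 times higher without GA3 3 h replicate 1 and over 1.5 times lower without GA3 3 h replicate 2. In ga1-5, XERICO, a gene induced by DELLA proteins, fell by 1.06 at 1 h and by 1.13 at 3 h (SE 0.17, adjusted p = 0.000165). The gibberellin receptor gene GID1B fell by 1.51 at 1 h and by 1.25 at 3 h (adjusted p = 0.0373). AT5G17760 fell by 1.08, and XTH32, a cell wall enzyme gene, fell by 0.77. The 3 h calls of GID1B and XTH32 were lost without any 1 of their 4 arrays (adjusted p from 0.137 to 0.766 and from 0.312 to 0.447), and that of AT5G17760 without mock 3 h replicate 1, mock 3 h replicate 2 or GA3 3 h replicate 2 (0.301, 0.156 and 0.872). No early auxin gene passed in ga1-5 over all probe sets. GH3.3 passed adjusted over the list alone at 1 h and 3 h (log2 changes 0.97 and 0.91), 1 gene at each time, and the list shifted upward (camera adjusted p = 0.0313). In Col-0, XERICO fell by 0.91 at 3 h (adjusted p = 0.0117), a call lost without mock 3 h replicate 1, mock 3 h replicate 2 or GA3 3 h replicate 2 (adjusted p = 0.0957, 0.21 and 0.365), and GID1B had a log2 change of -0.52 that did not pass. Col-0 had 0 calls at 3 h with only the arrays of the sets used and on the deposited scale, with an adjusted p for XERICO of 0.82 and 1. In ga1-5 the deposited scale also ended the calls of XERICO, GID1B, AT5G17760 and XTH32 (0.406, 1, 0.594 and 1), quantile normalization those of GID1B and XTH32 (0.0597 and 0.0618), the fit without a variance trend that of XTH32 (0.0584), and the arrays of the sets used alone that of AT5G17760 (0.118). Of the 5 tested genes of the list, 1 fell in Col-0 and 2 in ga1-5 at 3 h (1 and 3 adjusted over the list alone), and the list shifted downward in both (camera adjusted p = 1.56e-08 and 5.22e-12). The time course gave 4 calls in Col-0, 17 with the replicate block, and 22 in ga1-5. The Col-0 count was 1 without GA3 3 h replicate 2 and 2 without mock 3 h replicate 1. The ga1-5 count was 35 without mock 30 min replicate 2 or mock 1 h replicate 2, 11 without mock 3 h replicate 1 and 10 without mock 3 h replicate 2. AT2G36200 was 3.99-fold above mock under GA3, 3.63-fold under ACC and 4.02-fold under BL in Col-0 at 3 h, and these comparisons share their mock arrays. Its mock mean was 8.517 at 30 min and 8.187 at 1 h but 6.545 at 3 h. Its treated means at 3 h (8.542, 8.405 and 8.551) lay near the earlier mock means, so its differences rest on the low mock level at 3 h. Its GA3 call was lost without mock 3 h replicate 1, mock 3 h replicate 2 or GA3 3 h replicate 2 (adjusted p = 0.0982, 0.215 and 0.396) and its ACC call without mock 3 h replicate 2 or ACC 3 h replicate 2 (0.0979 and 0.0955). With only the arrays of the sets used its calls under GA3, ACC and BL ended (0.82, 0.172 and 0.0651), on the deposited scale those under GA3 and ACC (0.267 and 0.079), and at the 50% pseudocount that under GA3 (0.115).

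ABA gave the most calls. SAG29, a sugar transporter gene of senescing tissue, rose 144-fold at 3 h (log2 change 7.17, SE 0.57, adjusted p = 2.03e-13), and 69.1-fold and 302-fold without mock 3 h replicate 1 and 2, whose levels lay far apart (mock mean 7.21, SD 1.5). All 3 tested genes of the dehydration response, COR15A, COR47 and LEA4-5, rose at 1 h and at 3 h, also adjusted over the list alone, and reached 49.5-fold, 3.64-fold and 125-fold at 3 h (camera adjusted p = 1.1e-07). LEA4-5 was at 211-fold without mock 3 h replicate 1 and 74-fold without replicate 2. PUB19, a ubiquitin ligase gene, rose 53-fold. UGT72E1, a glycosyltransferase gene, fell by 3.51 (SE 0.26), and the expansin gene EXPA8 fell by 3.24. Auxin-conjugating GH3.3 rose 6.12-fold under ABA at 3 h. Calls went from 54 at 30 min to 450 at 1 h and 4615 at 3 h, and 391 of the 450 were also called at 3 h. With the replicate block they were 113, 754 and 5734, and leaving out 1 of the 4 arrays compared gave 25 to 50, 221 to 399 and 3330 to 3751. The median of all probe sets at 3 h was -0.16. The split of 1756 rises and 2859 falls became 2066 and 1922 when array medians were subtracted, with a median of -0.05, and 1073 and 985 on the deposited scale without rescaling. The time course held 3551 calls.

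MJ raised OPCL1, an enzyme gene of jasmonate synthesis, from 30 min on. It rose 7.24-fold at 30 min, 12-fold at 1 h and 4.81-fold at 3 h (adjusted p = 1.69e-09). The lectin gene JAL23 rose 54.5-fold at 3 h (SE 0.59) and JRG21 23.9-fold (14.9-fold without mock 3 h replicate 1 and 38.3-fold without replicate 2). Of the 2 tested genes of jasmonate response, THI2.1, a thionin gene, rose 3.85-fold at 3 h, and the defensin gene PDF1.2 had a log2 change of 0.72 that did not pass (adjusted p = 0.8). That is 1 gene, and 1 adjusted over the list alone, and neither passed at 30 min or 1 h. UGT74B1, of glucosinolate synthesis, rose 2.29-fold. The growth-related XTH19 fell by 1.99 (SE 0.30). Of the 315 calls at 30 min, 264 were called at 1 h, all in the same direction. Leaving out 1 of the 4 arrays compared gave 161 to 267 calls at 30 min and 869 to 1086 at 3 h. At 3 h 668 rose and 692 fell, which became 762 and 422 with array medians subtracted and 357 and 167 on the deposited scale without rescaling. The time course held 1679 calls.

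ACC raised ARL, a gene of organ growth, 4.16-fold at 1 h and 3.33-fold at 3 h (SE 0.27, adjusted p = 8.03e-05). RTE1, which acts on an ethylene receptor, rose 2.71-fold at 3 h, and EIN3 had a log2 change of 0.02 that did not pass. Of these 3 tested genes 2 rose at 3 h, and 2 adjusted over the list alone (camera adjusted p = 0.000183). RALFL18 rose 5.03-fold, a call lost without any 1 of its 4 arrays (adjusted p from 0.0657 to 0.165), with only the arrays of the sets used (0.0509), at the 2% pseudocount (0.13) and on the deposited scale (0.211). AT1G29660 fell by 2.19 (SE 0.26). The call of ARL at 3 h ended on the deposited scale (adjusted p = 0.0765). The time course held 198 calls, and 124 without ACC 1 h replicate 1. Leaving out 1 of the 4 arrays compared gave 10 to 49 calls at 1 h. At 1 h 27 rose and 6 fell, which became 21 and 25 with array medians subtracted (median of all probe sets 0.05 and then -0.10) and 6 and 0 on the deposited scale without rescaling.

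**Figure D2:**
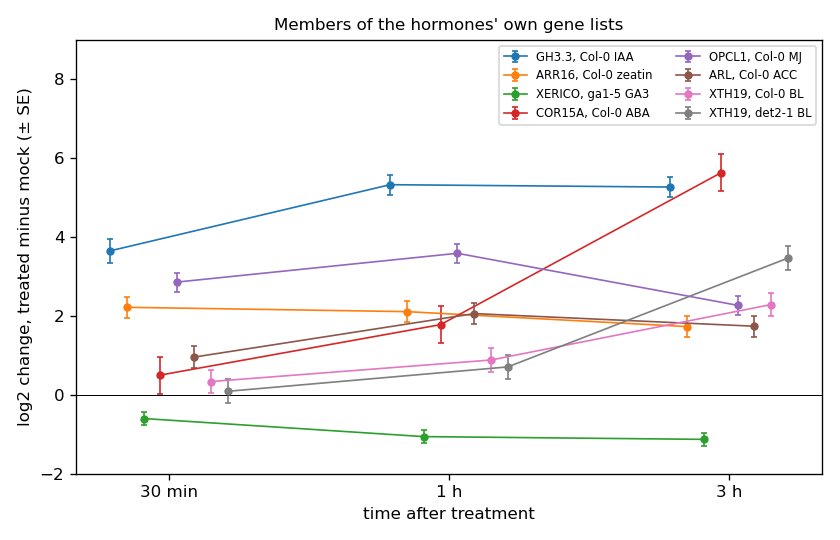
Log2 change of 7 genes from the hormones' own lists against mock at 30 min, 1 h and 3 h, with bars of 1 SE from the fit and XTH19 drawn for both genotypes. GH3.3 is at 3.65 by 30 min, and COR15A reaches 5.63 at 3 h.

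BL raised XTH18, XTH19, XTH33 and EXO in both genotypes at 3 h. XTH19, a wall-modifying enzyme gene, rose 4.9-fold in Col-0 and 11.1-fold in det2-1 (log2 changes 2.29 and 3.47, SE 0.30). XTH18 rose 2.5-fold and 4.45-fold, XTH33 3.16-fold and 6.14-fold, and EXO, a growth gene, 4.27-fold and 6.25-fold. The Col-0 call of XTH18 was lost without mock 3 h replicate 1 or BL 3 h replicate 2 (adjusted p = 0.139 and 0.0974) or on the deposited scale (0.0969). The expansin gene EXPA8 did not pass, with log2 changes of 0.95 (adjusted p = 0.775) in Col-0 and 2.42 (adjusted p = 0.0532) in det2-1, where it passed with the replicate block (adjusted p = 1.52e-06). The expansin-like genes EXLA2 and EXLA1 rose 14.7-fold and 10.3-fold in det2-1. AT5G57785 fell by 2.51 in Col-0 and fell by 2.81 in det2-1. The list of gibberellin receptors and DELLA-induced genes shifted upward in Col-0 (adjusted p = 0.0186), where 2 of its 5 tested genes rose at 3 h, and 2 adjusted over the list alone, BHLH137 (AT5G50915) by 3.14-fold and XERICO by 1.67-fold. Of the 3 tested growth genes 2 rose at 3 h in each genotype (2 in Col-0 and 3 in det2-1 adjusted over the list alone). The list shifted upward in det2-1 (camera adjusted p = 8.19e-09) and in Col-0 (adjusted p = 0.0193, but adjusted p = 0.106 with an estimated correlation). The other calls named for the Aux/IAA, growth and ethylene lists held with the estimated correlation (0.0538, 0.328 and 0.307). For the early auxin, dehydration and gibberellin lists the estimate was 0, below the fixed value of the main test. There the check is laxer than the main test, so it does not test those calls. Without Col-0 BL 3 h replicate 2, BL 1 h replicate 2 or mock 1 h replicate 1, the adjusted p of the growth list in Col-0 was 0.098, 0.0593 and 0.051.

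The time course held 614 calls in Col-0 and 542 in det2-1, the latter 1095 with the replicate block. The Col-0 count was 367 without mock 1 h replicate 2, 373 without BL 1 h replicate 1, and 1131 when array medians were subtracted. At 1 h in Col-0 88 rose and 76 fell, which became 69 and 437 with medians subtracted (median of all probe sets 0.07 and then -0.10), 42 and 84 with quantile normalization and 4 and 11 on the deposited scale without rescaling. The det2-1 count was 348 without BL 3 h replicate 2 and 350 without mock 3 h replicate 2. Of the Col-0 calls 211 were also called in det2-1, where independent lists give 19.3, and all 211 had the same direction. At 30 min det2-1 gave 5 calls, 24 with the replicate block, and 2 to 66 when 1 of the 4 arrays compared was left out, highest without BL 30 min replicate 2. The same left 37 to 517 calls at 1 h in Col-0.

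The difference of the BL response between genotypes was called for 15 probe sets, and for 8 without the 4 det2-1 arrays at 30 min. The count was 27 without Col-0 BL 1 h replicate 2, 27 without det2-1 BL 1 h replicate 2 and 67 without det2-1 BL 30 min replicate 2. At 3 h AT1G29660 rose more in det2-1 (difference 2.04, SE 0.37, adjusted p = 0.00688), and AT5G01740 fell more (difference -1.93, SE 0.32). The first was not called without Col-0 mock 3 h replicate 2, Col-0 BL 3 h replicate 1, det2-1 mock 3 h replicate 2 or det2-1 BL 3 h replicate 2 (adjusted p = 0.113, 0.065, 0.111 and 0.0651), nor the second without det2-1 BL 3 h replicate 1 (0.0526), nor either with only the arrays of the sets used (0.0646). For GA3 no probe set was called by limma over the time course, with 351 at an unadjusted p under 0.05, where chance gives 863.1. A number below chance means that p-values ran large here, so the lack of calls does not show equal responses. GA3 within Col-0 (514) and within ga1-5 (609) also lay below it. The main fit leaves out the pairing found for GA3 in Col-0, and with the replicate block 2 differences were called. There were 3 calls without ga1-5 mock 30 min replicate 2, 2 without ga1-5 GA3 30 min replicate 2 or Col-0 mock 3 h replicate 1, and 1 without Col-0 GA3 30 min replicate 1 or 2, Col-0 GA3 1 h replicate 1, ga1-5 mock 1 h replicate 2 or ga1-5 GA3 1 h replicate 1. At 1 h alone 1 probe set was called, unnamed here and singled out after its values were seen, with a difference of -1.96 (SE 0.36, adjusted p = 0.0442) from log2 changes of -2.52 in ga1-5 and -0.56 in Col-0. It was 0 with quantile normalization and on the deposited scale. The differences at XERICO and GID1B were not called.

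IAA in Col-0 and BL in det2-1, which share no mock arrays, had 103 called probe sets in common against 16.6 for independent lists, and 61.2% of them moved in the same direction. Rises in both numbered 59 against 7.03 for independent lists, and 25 and 15 moved in opposite directions. Across all 17262 probe sets, which are not independent, the changes correlated at 0.042 (Pearson) and -0.0185 (Spearman). Of the calls shared with BL in det2-1, 68% of 25 for zeatin, 41.2% of 257 for ABA, 45.7% of 186 for MJ and 9.3% of 43 for ACC moved in the same direction. Independent lists give 7.32, 111, 52.7 and 6.22 for these, so an excess of shared calls was not particular to IAA. GA3 had 2 calls in common between Col-0 and ga1-5, and 1 without Col-0 GA3 3 h replicate 2.

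Mock seedlings of ga1-5 had 3840 probe sets higher and 3453 lower than Col-0, and those of det2-1 2301 and 2379. Genotype coincides with array set, and these cannot be told apart. ICL, the isocitrate lyase gene of fat mobilization, was 79.6-fold higher in ga1-5 (SE 0.57) and 6.05-fold higher in det2-1. AOP3, of glucosinolate synthesis, was 14.2-fold and 23.7-fold higher. The plastid genes atpB and psaB were lower in det2-1, with log2 differences of -4.46 and -3.84. The log2 ratio of 3' to 5' signals of the GAPDH control averaged 0.19 ± 0.23 (SD, n = 48 arrays) in Col-0, -0.47 ± 0.27 (SD, n = 12) in ga1-5 and -0.34 ± 0.26 (SD, n = 12) in det2-1. It also differed by treatment within Col-0. In replicate 1 it was 0.366 to 0.565 for mock and -0.283 to -0.135 for ACC and BL over the times. In replicate 2 it was 0.292 to 0.37 for mock, 0.0765 to 0.35 for ACC and -0.171 to 0.407 for BL. For MJ the ratio was -0.176, -0.108 and 0.371 at 30 min, 1 h and 3 h in replicate 1, and 0.333, 0.0955 and 0.472 in replicate 2. Whether these differences bear on the calls of ACC, BL, MJ or other treatments was not tested. On the deposited scale without rescaling, 15579 probe sets were higher and 317 lower in ga1-5, and 15522 and 203 in det2-1, with medians of all probe sets of 1.23 and 1.05.

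Mock seedlings at 3 h and 30 min gave 0 calls by limma, with 684 probe sets at an unadjusted p under 0.05. Chance gives 863.1, so p-values ran large here too, and the lack of calls does not show equal levels. There were 3 without ga1-5 mock 30 min replicate 2 and 2 without det2-1 mock 3 h replicate 2. The root markers EXPA7 and EXPA18 and the shoot markers LHCB4.1 and LHCB4.2 passed under no treatment at 3 h. The clock gene GI did not pass under any treatment at that time. Of the rapid stress genes, ZAT10 rose by 2.27 under ABA and 2.02 under MJ on the log2 scale, and CML38 by 2.68 under MJ.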

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

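The tests of exchanged labels at 30 min and 2 of the 3 tests of the ACC array (0.353 and 0.594), and the alternative without the det2-1 arrays at 30 min, were chosen after the results were seen. The BL response differed between det2-1 and Col-0 at 15 probe sets by the interaction test, and 4 of them name 1 gene: AT5G65300 (adjusted p = 0.00647), AT5G01740 (adjusted p = 2.4e-05), BRH1 (adjusted p = 1.77e-05) and AT1G29660 (adjusted p = 0.0253). BRH1 had log2 changes of -0.88, -1.67 and -0.86 over the times in Col-0 and of 0.55, -0.61 and -0.68 in det2-1. AT5G01740 went from 0.87 at 30 min to -3.36 at 3 h in det2-1. Among 100 splits of the arrays within times and genotypes, 36 gave as many calls, and the highest other split gave 1102. The 7 highest turned the mock and BL labels of det2-1 at 3 h and kept those of Col-0, so that a response in both genotypes counts as a difference, and this count does not measure chance. Without the det2-1 arrays at 30 min 8 probe sets were called, of which 6 were among the 15. For GA3 all 100 splits gave at least the real 0 calls, with at most 34.

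The reversed det2-1 values at 30 min may come from exchanged mock and BL labels. In Col-0 BL at 30 min 10 probe sets rose and 13 fell, against 5 and 25 with quantile normalization and 0 and 1 on the deposited scale. Of the 23 called in the main fit, the 19 without a missing value on any array were used. They rose or fell by 1.25 on average there. Over these 19 the signed change in det2-1 averaged 0.018 (bootstrap SD 0.0978), with 9 of opposite sign, so its sign is open. The same probe sets responded by 0.552 at 1 h and 0.518 at 3 h in det2-1. The value at 30 min lies far from a response of that size with exchanged labels, and as far with the labels as given. It therefore does not decide between them, and a small response stays open under either. The arrays were scored with 3 signatures in all, chosen after the result was seen. Probe sets called at 1 h or 3 h, again only those without a missing value, gave -0.0658 (SD 0.0151, 220 of 361 opposite) for Col-0. Those called in det2-1 gave -0.0411 (SD 0.0108, 404 of 718 opposite). All these SDs resample probe sets on the same arrays and do not measure the spread between arrays. The BL arrays, replicates 1 and 2, were at -0.11 and -0.0213 for the Col-0 signature. For the det2-1 signature they were at -0.0748 and -0.0073, so both negative means rest mostly on replicate 1. The reversed genes above were picked by the interaction test and cannot decide this. The labels were kept, and no biological explanation was tested.

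For mutant against Col-0 mock seedlings, 1 of 100 splits, the real one, gave as many calls for ga1-5 (7293, highest other 4384) and for det2-1 (4680, highest other 2214). This excludes chance only where the arrays compared are exchangeable. They come from separate sets, and a set effect would also make the real split the highest. Taken against separate parts of the Col-0 mock arrays, the 2 mutant differences correlated at 0.412 across probe sets, between the bounds of 0.2 and 0.5 set beforehand for a processing difference between sets. With shared Col-0 arrays the correlation was 0.522, against 0.499 simulated with no effect, and the covariance 0.147 against 0.0155. For RNA or labelling quality the GAPDH ratio differed by -2.53 SDs of the Col-0 arrays and the actin ratio by -0.481. The bounds set beforehand did not say how to weigh disagreeing controls, so quality, processing and genotype cannot be told apart.

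ACC 3 h replicate 1 carries the scale of the 30 min set, and was tested as an array taken at 30 min. Over 66 probe sets called for ACC at 3 h without this array, its mean signed deviation from the 3 h mock arrays was 0.931, against 0.337 and 0.335 for the ACC 30 min arrays and 1.39 for the other 3 h array. It exceeded the higher 30 min array by 0.594 (bootstrap SD 0.0676) and at 60 of the 66, which argues against a sample taken at 30 min. The bootstrap treats the probe sets as independent, and no other treatment was scored this way for reference. The tests run before this comparison did not decide. The array's position between the 30 min (0) and 3 h (1) arrays was 0.361, above every 30 min array (0.0488 to 0.251) but under the bound of 0.5. It was also above the lowest other 3 h array (BL, 0.322), so it met both bounds set beforehand. On 96 probe sets that differ between ACC at 3 h and 30 min it was 0.353 (SD 0.042), below the other hormones at 3 h (0.406 to 0.811). Of the 30 min arrays scored likewise, zeatin, BL and GA3 lay above it (0.383, 0.37 and 0.769). IAA, ABA and MJ lay below (0.212, 0.136 and 0.187), so this position does not part the times. Why this array carries that scale stays open, and no biological explanation was tested.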

How the results depend on the processing

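Deposited signals without rescaling, leaving out probe sets with impossible values and leaving out det2-1 at 30 min were chosen after seeing the data. Time-course, difference, mutant and mock counts and the overlaps below stayed within 1.5 times where not given. In settings that leave out an array, the lone array is assumed to vary like the other groups. The causes of these changes were not tested, and dim signals limit what can be called.

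With the replicate block, time-course calls were 954 for IAA, 582 zeatin, 17 GA3, 2702 MJ, 575 ACC, 1877 BL, 124 ga1-5 GA3 and 1095 det2-1 BL. The block gave 2 (GA3) and 81 (BL) genotype differences, 3 calls for mock over time, and overlaps of 254 (IAA with det2-1 BL), 485 (BL with det2-1 BL) and 12 (GA3). ABA gave 4803, ga1-5 8230 and det2-1 5949, within 1.5 times. It kept 524 of the 528 IAA, 3542 of the 3551 ABA and 1674 of the 1679 MJ calls and changed no list call. Among the genes run singly it changed 1 call, EXPA8 under BL in det2-1. Same-numbered arrays at 30 min, 1 h and 3 h correlated at 0.159, 0.308 and 0.0705 for MJ, 0.263, 0.314 and 0.0181 for ACC, 0.226, 0.303 and 0.0375 for BL in Col-0 and 0.248, 0.0962 and 0.0539 for ga1-5 GA3. These did not pass 0.1 at every time and were not taken as paired.

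At single times the block gave 493 (30 min) and 2241 (3 h) for MJ, 82 for ACC at 1 h, 928 and 659 for BL at 1 h and 3 h, and 127 and 1352 for det2-1 BL. Without rescaling there were 39 for IAA and 22 for ABA at 30 min, 167 for ABA at 1 h, 133 for MJ at 30 min, 64 for BL at 3 h, and 30 and 283 for det2-1 BL at 1 h and 3 h. With only the arrays of the sets used there were 50 and 279 for IAA at 30 min and 3 h, 33 and 282 for ABA at 30 min and 1 h, 789 for MJ at 3 h, 8 for ACC at 1 h, 40 and 76 for BL at 1 h and 3 h, and 0 and 26 for det2-1 BL at 30 min and 1 h. The 2% pseudocount gave 10 for det2-1 BL at 30 min. Leaving out 1 array gave 24 to 82 for det2-1 BL at 1 h.

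On deposited signals without rescaling the time courses gave 169 for IAA, 40 zeatin, 0 GA3, 1347 ABA, 718 MJ, 15 ACC, 78 BL, 12 ga1-5 GA3 and 214 det2-1 BL. There were 9 BL differences, 15896 calls for ga1-5 and 15725 for det2-1, and overlaps of 39, 58 and 0. With only the arrays of the sets used, calls were 142 for zeatin, 1 GA3, 125 ACC, 336 BL and 46 ga1-5 GA3, and 1 GA3 difference. The union of single times gave 7 for GA3 and 400 for BL. Subtracting array medians gave 1131 for BL and 1 for mock over time, and quantile normalization 13 for ga1-5 GA3. GA3 differences were 2 without a filter, 3 at the 2% and 1 at the 50% pseudocount, and 1 without the probe sets with impossible values. The 2% pseudocount gave 9 for GA3. Without det2-1 at 30 min BL differences were 8, and mock over time gave 1. The growth list under BL in Col-0 had an adjusted p of 0.106 with an estimated correlation.

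Leaving out 1 array at a time gave 2610 to 3576 for ABA, 124 to 199 ACC, 367 to 774 BL, 1 to 5 GA3, 390 to 526 IAA, 1407 to 1652 MJ, 142 to 226 zeatin, 348 to 661 det2-1 BL and 10 to 35 ga1-5 GA3. BL differences were 12 to 67, highest without det2-1 BL 30 min replicate 2, and GA3 differences 0 to 3. Mock over time gave 0 to 3, det2-1 3815 to 4454 and ga1-5 6583 to 6962, and overlaps 75 to 118 (IAA with det2-1 BL), 161 to 231 (BL with det2-1 BL) and 1 to 2 (GA3). The list adjusted p was 0.0031 to 0.098 for growth genes under BL in Col-0 and 7.98e-11 to 1.38e-07 in det2-1, 1.74e-05 to 0.00281 for ethylene genes under ACC, and 2.6e-08 to 7.13e-07 for dehydration genes under ABA. It was 3.83e-08 to 1.98e-06 for Aux/IAA and 8.6e-46 to 7.14e-33 for early auxin genes, and 9.94e-09 to 2.06e-06 (Col-0) and 1.84e-12 to 1.15e-08 (ga1-5) for gibberellin genes. EIN3 under ACC turned to -0.00275 with medians subtracted and lay between -0.0385 (without ACC 3 h replicate 2) and 0.0735 with arrays left out. PDF1.2 under MJ lay between -0.676 (without mock 3 h replicate 1) and 2.12, and neither gene was called. Of the named genes called, 0 changed direction under the settings run for single genes. For the largest rises and falls against mock or Col-0 the naming rule fixed this in advance where 1 array was left out. Their arrays all lay on 1 side of the arrays compared, so leaving out 1 could not turn the sign.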

Other observations

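Among 33 gene families chosen after the numbers of calls had been seen, the xyloglucan endotransglucosylase family (XTH, 8 tested genes) shifted upward under BL in det2-1 (camera adjusted p = 3.75e-07) and in Col-0 (adjusted p = 0.0156). XTH16, XTH18, XTH19 and XTH33 rose at 3 h in both. These include genes already in the fixed list of growth genes. The PUB ubiquitin ligase family (8 tested genes) shifted upward under IAA (adjusted p = 0.000232), where PUB25 alone rose at 3 h.

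Splits of the arrays within times were counted for each time course. For the unpaired treatments there were 27. Only the real split gave as many calls for MJ (1679, highest other 1477), ACC (198 and 116) and BL in Col-0 (614 and 358), 1 of 27 each, which excludes chance at 0.05 where the arrays of a time are exchangeable. Their same-numbered arrays correlated at 0.159 to 0.314 at 30 min and 1 h, so that condition was not fully met. For ga1-5 GA3 4 of 27 did (22, highest other 52), so chance is not excluded, and the highest grouped the 30 min arrays by replicate number. For the paired treatments the splits that part as many pairs number 8, too few for a share under 0.05, and were added after the results were seen. The real count and the highest other were 528 and 442 for IAA, 233 and 137 for zeatin, 3551 and 3365 for ABA, 542 and 527 for BL in det2-1 and 4 and 4 for GA3 in Col-0, so that 2 of 8 reached the real count for GA3 and 1 of 8 for the others. With the replicate block they were 954 and 840, 582 and 448, 4803 and 4546, 1095 and 1038, and 17 and 21. Among all 27 splits, those that group arrays by replicate number gave up to 3631 for ABA and 695 for BL in det2-1. Mock seedlings over time gave at least the real 0 calls in 100 of 100 splits, with at most 2 in another.

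More BL calls at 3 h in det2-1 (771, and 429 to 511 when 1 of the 4 arrays compared was left out) than in Col-0 (266, and 121 to 208) raised the hypothesis of a larger response in det2-1. Among 164 probe sets called at 1 h in Col-0, the median of the signed 3 h changes was lower in det2-1 by 0.058 (difference -0.058, bootstrap SD 0.0602), and among 65 called at 1 h in det2-1 it was higher by 0.492 (SD 0.102). Set beforehand, a larger response had to show under both choices. A median larger in Col-0 under either choice counted against it. The first choice met the latter, with medians of 0.28 in Col-0 and 0.222 in det2-1. That difference lies within 1 bootstrap SD, but the bootstrap spread was added after the first value was seen. With that margin a larger response stays open. By the median of paired differences, a statistic not chosen beforehand, the first value was 0.0652.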
